A study of Daphnia magna with 23 samples.

How the data were processed

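The series holds 23 one-colour microarrays of total RNA from whole Daphnia magna, with 20 animals per replicate. Per the labels, RNA was extracted on columns, 0.4 ug was amplified and labelled with Cy3, and the exposure followed a standard chronic toxicity protocol for daphnids. The toxicity test had 1 animal in each of 10 chambers per treatment, and doses were picked from a test in 50 ml beakers, per the study text. The groups and replicate numbers come from the sample titles: 6 arrays of solvent control, 6 at 0.004 mg/L, 5 at 0.12 mg/L and 6 at 1.85 mg/L TNT.

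Each array has 15744 spots, of which 536 are controls. The other 15208 hold 14338 probes, 870 of them spotted in duplicate, with 12648 probes of 50 bases and 1690 of 60 bases. Per the file headers, the intensity values were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted background and detrended the signal within each array; nothing was normalized between arrays in these files. Values near background were replaced by surrogates in that software, on 2 to 257 spots of an array outside the weak arrays, and on 3029 and 1248 spots of these. Other columns of the deposited files hold flags, with values of 0 or 1, for outlier, saturated and well above background spots.

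A deposited table gives the authors' own log2 values for 14398 rows and the 23 arrays. Every probe in it has a median of 0 and every column the same mean, -0.0133; column medians ran from -0.0471 to 0.159. Set against log2 of the processed signal, quantile normalized and centred on each probe's median, every column had a correlation of at least 0.9976, which settles its log scale, centring and direction; the exact steps are not given in the sources used here. These values served as an alternative. The 23 deposited column medians were 0.0374, 0.00237, 0, -0.0126, -0.0116 and 0.159 for 0.004 mg/L replicates 5, 6, 3, 4, 1 and 2. They were 0.0241, 0.0230, -0.00821, 0 and -0.00760 for 0.12 mg/L replicates 5, 6, 3, 4 and 1, and 0, 0, 0, -0.0291, -0.0471 and -0.0294 for 1.85 mg/L replicates 6, 5, 3, 4, 1 and 2. For solvent control replicates 5, 6, 3, 4, 1 and 2 they were 0.00695, 0.0187, 0, 0, 0.145 and 0.

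For the main values, log2 of the processed signal was taken, each array's 75th percentile was subtracted, spots with an outlier flag were left out and duplicate spots were averaged. Control spots were left out. Probes well above background on at least 5 arrays, the size of the smallest group, were kept (13920). Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 23 arrays, so that the 4 groups share 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were each of the 3 doses against solvent control, 1.85 against 0.004 mg/L, an F test over the 3 differences from control, the number of probes with opposite changes at 0.004 and 1.85 mg/L, and the correlations of log2 differences between doses. Choices of test, filter, threshold and most alternatives were fixed before the data were examined.

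Each array had a signal at the 75th percentile of 806.3 to 1344 scanner units, except 241.8 on solvent control replicate 1 and 528.1 on 0.004 mg/L replicate 2. The slopes of the spike-in curves on these arrays, 0.820 and 0.865, lay below those of the other arrays (0.941 to 1.084). They stay in the main results, because the design had been fixed; the results without them were added after the data had been seen.

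The design IDs carry the description "Unknown" on every spot, no ID matched the reference table (0 of 14338), and no genome was used. The 26 gene lists fixed beforehand, among them yolk, hemoglobin, cuticle, detoxification and digestive genes, could therefore not be matched to probes, and none was tested. The rule for named probes was, where names are given, the largest changes among named genes with the same sign on every slide, and without names 2 probe IDs that rose and 2 that fell. It was applied per comparison, to the largest differences past the threshold with one sign on all 3 slides. Other probes are named where a count was 5 or fewer, or where they had been called at another dose, and were chosen after their values were seen.

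The arrays lie on 3 slides of up to 8 arrays, each scanned once. Slide 1 holds replicates 5 and 6, slide 2 replicates 3 and 4 and slide 3 replicates 1 and 2 of each group, without a replicate 2 at 0.12 mg/L, so every slide holds all 4 groups. Alternatives were normexp background correction (offset 50) of the mean and background signals, quantile normalization, other filters on dim probes, slide or replicate number as a block, each slide alone, only the groups compared, eBayes with trend and robust, array weights, the deposited values, other thresholds and leaving out each array. After the data had been seen, fits without the 2 weak arrays, without these and 1.85 mg/L replicate 1, with row and column on the slide, and a contrast of 0.004 and 0.12 mg/L with control and 1.85 mg/L were added.

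The fit was tested on simulated data for 1.85 mg/L against control, with permuted residuals of the 13920 probes and 200 probes changed in each of 20 simulations. With all arrays, 9.7% of changes of 1.5-fold, 37.9% of 2-fold, 83.3% of 4-fold and 94.5% of 8-fold were recovered; without the weak arrays, 26.1%, 57.8%, 90.5% and 97.2%. The median number of false calls was 0 with all arrays (highest 15) and 1 without the weak ones (highest 58). The permutation moved arrays between slides, unlike the real groups, which each lie on every slide. Slide differences may therefore have affected these numbers. Chance groupings were counted over 100 splits of the arrays and over splits that exchanged arrays only within a slide (100, or all 36 where no more exist). In addition, unchanged groups against the same controls were simulated 100 times by permuting residual arrays, for the correlations and overlaps. Runs with the measured changes of 1 dose added were chosen after the overlap had been seen. BLAST+ 2.17.0 was used to find probes that share sequence, and Python 3.11.15 with NumPy 2.4.6 and matplotlib 3.10.9 for the plots.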

Results

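The data are gene expression measurements on whole Daphnia magna, a small freshwater crustacean (water flea) used in toxicity testing, after exposure to TNT (2,4,6-trinitrotoluene, an explosive). According to the study text, the animals were younger than 24 h at the start of the test, and the exposure for the arrays held 5 nominal levels, from 1.85 through 0.44, 0.12 and 0.02 down to 0.004 mg/L. RNA from 3 of these levels and from a solvent control was hybridised, 1 sample per array, to 23 one-colour arrays. There were 6 arrays of solvent control, 6 at 0.004 mg/L, 5 at 0.12 mg/L and 6 at 1.85 mg/L. Each replicate pooled 20 animals. The labels do not say whether replicates came from separate exposure vessels, so the p-values measure the spread between these pools.

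Of the 14338 probes, 13920 were well above background on at least 5 arrays and were tested. The probes carry only a design ID. No ID matched a gene name in the tables used here, so probes are given by ID and sequence, without a gene or a position in a genome. Signal is given as log2 of the scanner software's processed signal minus the array's 75th percentile, with the SD between arrays.

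The share of spots well above background lay between 89.56% and 99.77% on 21 arrays. It was 49.68% on solvent control replicate 1 and 79.44% on 0.004 mg/L replicate 2. On these arrays, called weak arrays from here on, duplicate spots of 1 probe differed by a median of 0.411 and 0.465 on the log2 scale, against at most 0.170 on the others. The number of arrays and the 2 weak arrays limit the precision, so the number of probes called in each comparison is given over all 23 arrays and without the weak arrays.

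**Figure D1:**
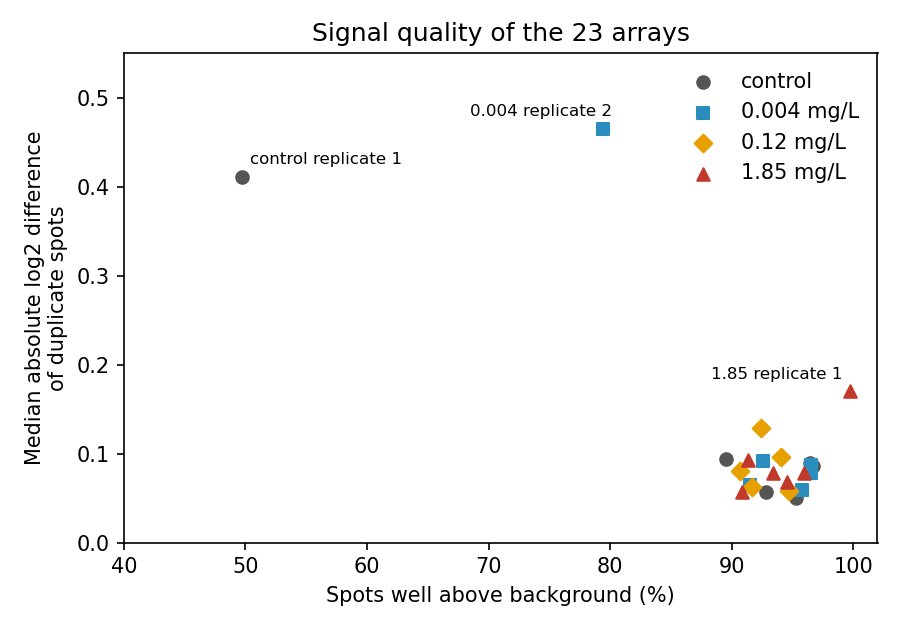
Percent of spots well above background (x axis) against the median absolute log2 difference between duplicate spots of a probe (y axis), 1 point per array, with marker and colour by group. Solvent control replicate 1 (49.68%, 0.411) and 0.004 mg/L replicate 2 (79.44%, 0.465) lie apart from the other arrays, and 1.85 mg/L replicate 1 (99.77%, 0.170) has the highest share.

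The first comparison set 0.004 mg/L, which the study took as its hormetic dose (a low dose that stimulates where a higher dose harms), against solvent control. Signal fell for 5 probes and rose for 0. DM05878P1 (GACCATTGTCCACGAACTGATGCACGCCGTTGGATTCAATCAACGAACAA) fell from 0.37 ± 1.57 (SD, n = 6) in controls to -3.93 ± 0.67 (SD, n = 6), a 19.6-fold lower signal (log2 difference -4.30 ± 0.64, SE; adjusted p = 0.00646), and it was well above background on 5 of the 6 arrays at this dose. DM01742P2 (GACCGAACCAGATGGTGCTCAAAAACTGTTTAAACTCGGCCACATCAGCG) fell from -0.56 ± 0.87 to -3.97 ± 1.13 (SD, n = 6 each), 10.6-fold, with an adjusted p of 0.00113. The remaining probes were named after their values were seen. DM08360P3 (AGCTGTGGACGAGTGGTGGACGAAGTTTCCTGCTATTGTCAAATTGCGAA) was at least 9.56-fold lower (log2 difference -3.26 ± 0.56, SE; adjusted p = 0.0266), and its spots were saturated on 5 of the 6 control arrays and on none at this dose. DM01138P4 (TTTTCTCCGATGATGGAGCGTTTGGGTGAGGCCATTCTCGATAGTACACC) was 3.66-fold lower (adjusted p = 0.0371) and DM11208P3 (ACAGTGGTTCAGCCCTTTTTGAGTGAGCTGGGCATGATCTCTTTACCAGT) 2.89-fold lower (adjusted p = 0.00836). Each of the 5 was lower at 0.004 mg/L on all 3 slides.

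The count came from a limma fit over all 23 arrays with Benjamini-Hochberg adjustment, and at an unadjusted p under 0.05 the number was 1136, or 740 without the weak arrays, where 696 are expected by chance. Without the weak arrays 6 probes passed, 1 higher and 5 lower, and 4 were shared; DM08360P3 then missed the threshold (adjusted p = 0.0751). Leaving out 0.004 mg/L replicate 5 gave 47 probes, replicates 6, 3 and 1 of the controls 10, 8 and 8, and replicates 4 and 2 of the controls 3 and 3. With the slide as a block 5 probes passed, and within slides 1, 2 and 3 alone 0, 0 and 0. Quantile normalization gave 2 higher and 9 lower probes and the deposited values 3 higher and 9 lower. Normexp background correction left 0, a fit of only the groups compared 0, row and column on the slide as terms 2, and the replicate number as a block 4, or 2 without the weak arrays. Array weights, in contrast, gave 683 probes, 215 higher and 468 lower, so neither the count nor the absence of rises held in every setting.

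At 0.12 mg/L, the intermediate dose, 3 probes rose and 6 fell against solvent control. All 5 probes that fell at 0.004 mg/L fell here too, where independent lists would share 0.00216 probes. Both comparisons use the same controls, which independent lists would not. With 3 controls for either dose, which leaves fewer arrays per comparison, the median shared over the 20 ways to divide the 6 was 0 and the highest 1. Unchanged groups simulated against the same controls shared 0 probes in each of 100 runs, and so did runs in which only 0.004 mg/L, or only 0.12 mg/L, was given its measured changes. The unchanged dose had a call in only 2 and 1 of those 100 runs, so shared controls alone seldom produced a call there. DM05878P1 was 14.9-fold lower (log2 difference -3.90 ± 0.67, SE; adjusted p = 0.0233), DM01742P2 10.9-fold (adjusted p = 0.00205) and DM08360P3, saturated on 5 of the 6 control arrays, at least 15.3-fold (adjusted p = 0.00702). DM01138P4 was 4.51-fold lower (adjusted p = 0.0155) and DM11208P3 2.71-fold lower (adjusted p = 0.0233). The sixth, DM12614P2 (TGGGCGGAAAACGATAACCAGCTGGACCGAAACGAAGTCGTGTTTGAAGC), was well above background on 6 of 6 control arrays and on 0 of 5 arrays at 0.12 mg/L. It was at least 12.8-fold lower (adjusted p = 0.0266), a bound from the control mean of -2.46 against a floor of -6.14, the mean over arrays of the lowest signal among probes well above background or the probe's own, if higher. Without solvent control replicate 1, the brightest control array for this probe, the control mean was -3.10 and the bound 8.25-fold. At 0.004 mg/L the mean of DM12614P2 was -6.3, with 2 of 6 arrays well above background, and the fall missed the threshold (adjusted p = 0.0797).

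The 3 rises at 0.12 mg/L were smaller. DM06319P2 (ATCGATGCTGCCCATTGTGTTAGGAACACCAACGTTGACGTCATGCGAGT) rose from -0.38 ± 0.36 (SD, n = 6) to 1.51 ± 0.64 (SD, n = 5), 3.70-fold (adjusted p = 0.0266). At 0.004 mg/L its mean was 0.92 ± 0.73, a difference that did not pass the threshold (adjusted p = 0.206). DM04653P1 (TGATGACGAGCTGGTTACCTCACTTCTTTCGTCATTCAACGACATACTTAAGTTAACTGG) rose 2.42-fold (log2 difference 1.27 ± 0.24, SE; adjusted p = 0.0441), and 5 of the 6 control arrays measured it above background. DM02677P3 (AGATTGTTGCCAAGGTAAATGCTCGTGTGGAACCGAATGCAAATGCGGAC), named after its values were seen, rose 2.18-fold (adjusted p = 0.0452).

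Without the weak arrays, 29 probes passed at 0.12 mg/L, 14 higher and 15 lower, among them all 9 found with every array. At an unadjusted p under 0.05 the numbers were 1100 with all arrays and 1260 without the weak ones. Leaving out single arrays moved the count to between 2 (0.12 mg/L replicates 4 and 6, solvent control replicate 4) and 22 (solvent control replicate 1). With the slide as a block 8 probes passed, within slide 1 alone 13, none of them among the 9, and within slides 2 and 3 alone 0 and 0. Quantile normalization gave 2 higher and 7 lower, the deposited values 9 higher and 7 lower. The replicate number as a block left 5, or 2 without the weak arrays, normexp 1, a fit of only the groups compared 2, and row and column as terms 2. Array weights gave 55 higher and 38 lower. A direct comparison of 0.12 with 0.004 mg/L in limma found 0 probes past the threshold, with all arrays and without the weak ones, and 413 and 585 at an unadjusted p under 0.05.

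At 1.85 mg/L, the dose chosen as toxic, 83 probes differed from solvent control, 37 higher and 46 lower. Of these, 50 differed at least 2-fold and 15 at least 4-fold, against 116 and 23 of the larger number found without the weak arrays. DM04155P3 (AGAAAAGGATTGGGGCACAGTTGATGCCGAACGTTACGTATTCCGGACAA) rose from -1.63 ± 0.38 to 1.34 ± 0.69 (SD, n = 6 each), 7.86-fold (log2 difference 2.98 ± 0.29, SE; adjusted p = 7.52e-06). Its lowest array at 1.85 mg/L, 0.56, lay above its highest control array, -1.15. DM04295P1 (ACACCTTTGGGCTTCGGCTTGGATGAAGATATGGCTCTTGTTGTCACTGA) rose 6.83-fold (adjusted p = 0.0447), from 0.39 ± 1.49 to 3.17 ± 0.56; its means at 0.004 and 0.12 mg/L, 2.98 and 2.97, were about as high, but those differences had adjusted p of 0.206 and 0.214. DM02756P2 (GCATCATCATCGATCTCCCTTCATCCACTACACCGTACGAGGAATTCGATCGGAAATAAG) fell 6.78-fold, from 1.77 ± 0.77 to -0.99 ± 0.61 (SD, n = 6 each; adjusted p = 0.0129). DM11411P3 (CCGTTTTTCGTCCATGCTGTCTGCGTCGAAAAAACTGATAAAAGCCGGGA) fell 5.43-fold (adjusted p = 0.0339) and was measured above background on 5 of 6 arrays in either group.

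The probes that were lower at 0.004 and 0.12 mg/L did different things at 1.85 mg/L. DM11208P3 was 5.32-fold higher than in controls (log2 difference 2.41 ± 0.24, SE; adjusted p = 7.52e-06). DM01742P2 stayed lower, 4.42-fold (adjusted p = 0.025). DM05878P1 and DM01138P4 did not differ from controls past the threshold: their log2 differences were -0.34 ± 0.64 and 0.10 ± 0.33 (SE), with adjusted p of 0.961 and 0.98. DM08360P3 was saturated on 5 of the 6 control arrays and on 3 of the 6 arrays at 1.85 mg/L, so its difference there was not measured.

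Without the weak arrays 422 probes differed between 1.85 mg/L and control, 237 of them higher, including all 83. With 1.85 mg/L replicate 1 left out as well, 171 were higher and 194 lower. With quantile normalization in place of the 75th percentile, the split was 31 higher and 43 lower with all arrays, and 186 higher and 299 lower without the weak ones; normexp gave 10 higher and 4 lower. The median difference over all probes was 0.012 with all arrays and 0.138 without the weak ones on the 75th percentile scale, and -0.039 and -0.015 after quantile normalization. At 0.004 and 0.12 mg/L the medians were -0.156 and -0.150 with all arrays and -0.024 and -0.047 without the weak ones, and with normexp 0.222 and 0.201. The named changes past the threshold with all arrays, none under 1.12 on the log2 scale, are larger than these shifts. With the slide as a block 65 probes passed, within slides 1, 2 and 3 alone 8, 0 and 0, and with the replicate number as a block 24 (71 without the weak arrays). The array's row and column on the slide as terms left 4 (28 without the weak arrays), and a fit of only the groups compared 23. Array weights gave 453 higher and 550 lower. Counts without single arrays lay between 26 (1.85 mg/L replicate 4) and 159 (0.004 mg/L replicate 2).

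**Figure D2:**
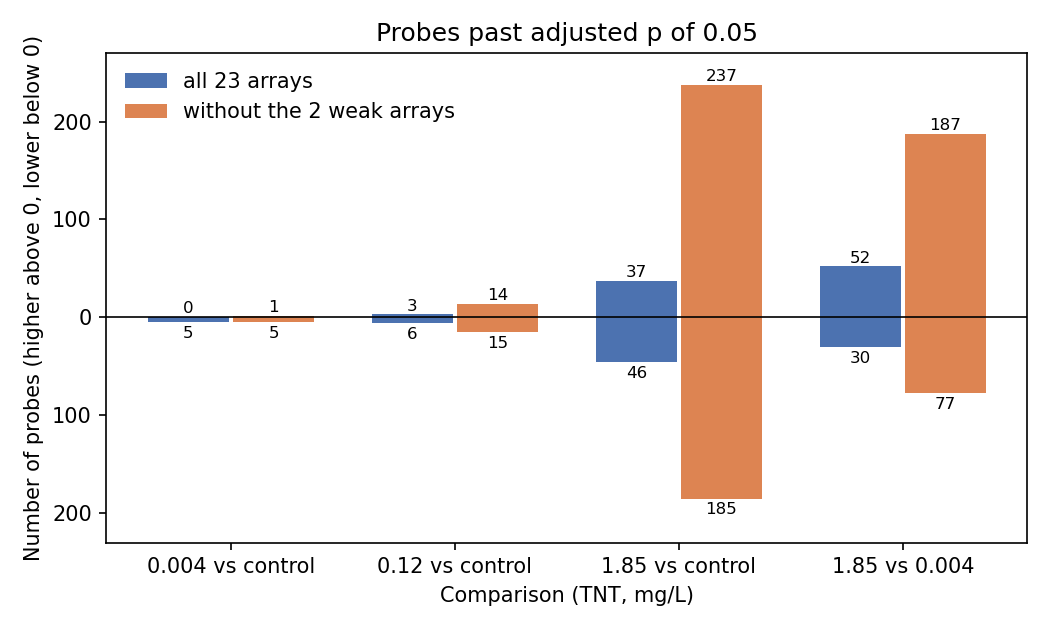
Number of probes past an adjusted p of 0.05 in 4 comparisons (x axis, TNT doses in mg/L), higher above 0 and lower below 0, with all 23 arrays (blue) and without the 2 weak arrays (orange). The comparison of 1.85 mg/L with control gave 37 higher and 46 lower probes with all arrays and 237 higher of 422 without the weak ones, against 0 higher and 5 lower at 0.004 mg/L with all arrays.

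Between the toxic and the hormetic dose, 82 probes differed, 52 higher and 30 lower at 1.85 than at 0.004 mg/L. DM05883P1 (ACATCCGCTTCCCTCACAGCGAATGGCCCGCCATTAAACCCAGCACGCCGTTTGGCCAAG) stood at 4.32 ± 0.08 at 1.85 mg/L and at 0.10 ± 0.52 at 0.004 mg/L (SD, n = 6 each), an 18.7-fold difference (log2 difference 4.22 ± 0.55, SE; adjusted p = 0.000212). In controls it spread from -1.40, on weak replicate 1, to 3.57, and the lowest of the other 5 was 0.793. DM05878P1 was 15.5-fold higher at 1.85 mg/L (adjusted p = 0.00214). DM04941P2 (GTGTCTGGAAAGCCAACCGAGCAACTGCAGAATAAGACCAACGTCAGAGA) was 16.9-fold lower at 1.85 mg/L (log2 difference -4.08 ± 0.59, SE; adjusted p = 0.000768), measured above background on 5 of 6 arrays there. DM02756P2 was 13.6-fold lower (adjusted p = 0.000212).

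Without the weak arrays 264 probes differed between these doses, 187 higher and 77 lower, sharing 81 with the list from all arrays. After quantile normalization the split was 41 higher and 52 lower with all arrays and 114 and 128 without the weak ones; the median over all probes had been 0.165 with all arrays and 0.152 without the weak ones on the 75th percentile scale. The deposited values gave 44 higher and 51 lower. With the slide as a block 89 probes passed, and within slides 1, 2 and 3 alone 5, 1 and 0. Normexp gave 25, row and column as terms 47, and the replicate number as a block 57. Array weights gave 2104 higher and 778 lower. Leaving out solvent control replicate 1 gave 236 probes and leaving out 1.85 mg/L replicate 6 gave 52. All 5, 9, 83 and 82 probes called in the 4 comparisons had the same sign on each of the 3 slides. They were called from the arrays of these same slides, which favours such a result.

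**Figure D3:**
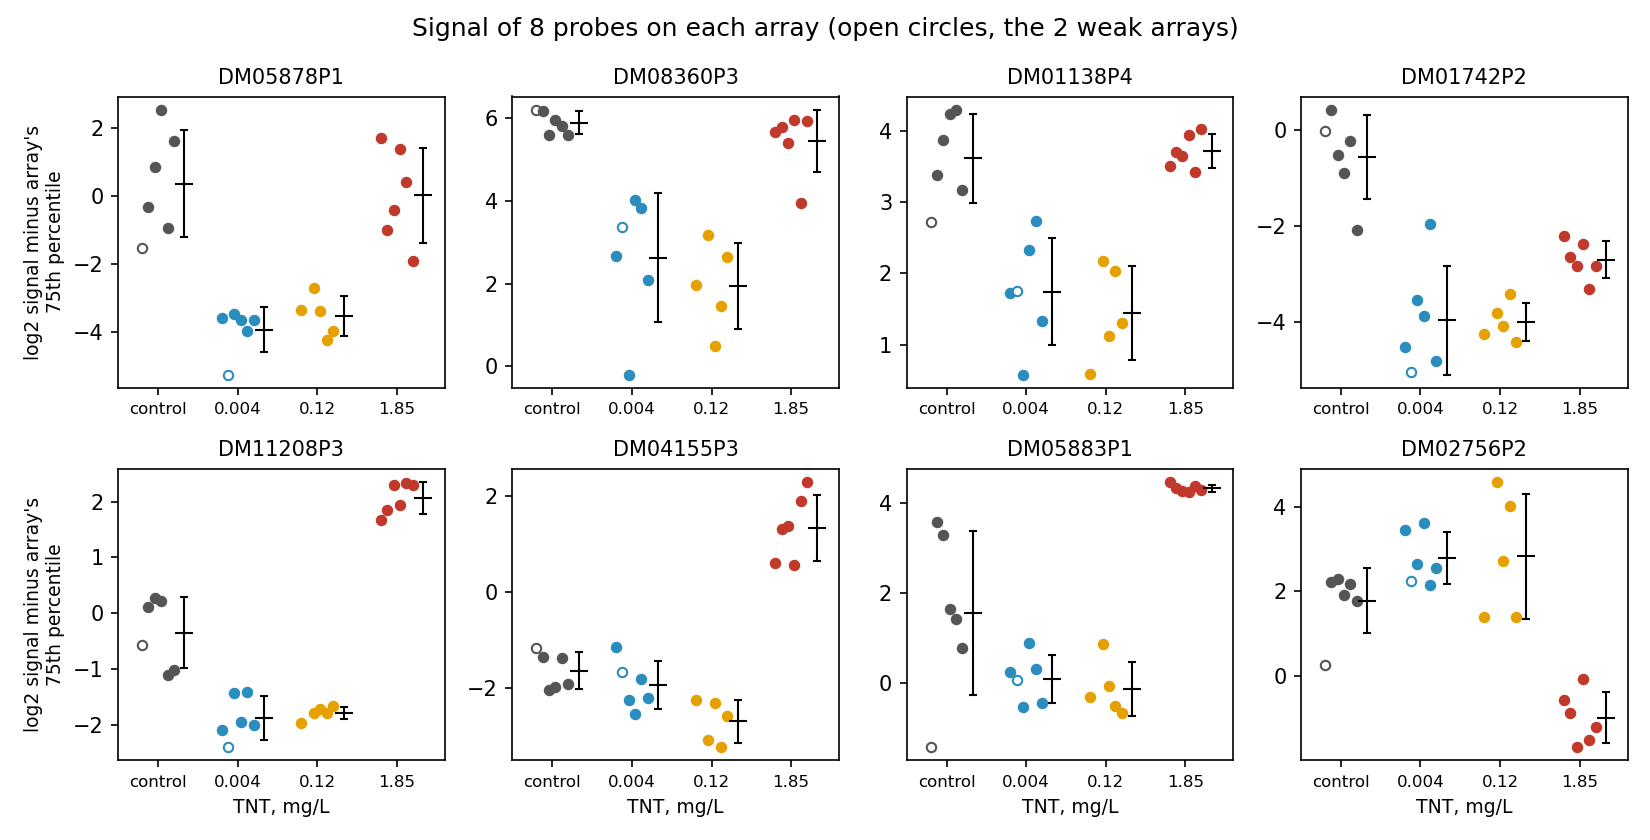
Signal (y axis, log2 minus the array's 75th percentile) of 8 probes in the 4 groups (x axis, solvent control and TNT dose in mg/L), 1 circle per array, open for the 2 weak arrays, with the mean and SD over all arrays of a group in black. DM05878P1, DM08360P3 and DM01138P4 are lower at 0.004 and 0.12 mg/L than in controls and at 1.85 mg/L; DM11208P3 is lowest at 0.004 mg/L (-1.88) and 0.12 mg/L (-1.79) and highest at 1.85 mg/L (2.06).

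Over all 4 groups, 97 probes passed the F test with all arrays and 294 without the weak ones, 24 with normexp, 44 with row and column as terms and 2095 with array weights. On 69 of the 97, and on 220 of the 294, the group mean farthest from the other 3 was that of 1.85 mg/L. Control was farthest on 17 and 52, 0.12 mg/L on 7 and 18 and 0.004 mg/L on 4 and 4. The question of a response that turns round with dose was put as a count of probes with a called change at 0.004 mg/L and a called change of the opposite sign at 1.85 mg/L. DM11208P3 alone met this, both with all arrays and without the weak ones. Its mean was -0.35 ± 0.63 in controls, -1.88 ± 0.39 at 0.004 mg/L, -1.79 ± 0.11 at 0.12 mg/L and 2.06 ± 0.29 at 1.85 mg/L (SD, n = 6, 6, 5 and 6). Leaving out any single array kept the count at 1, but it was 0 with normexp, with row and column as terms, and with the replicate number as a block without the weak arrays, and 15 with array weights. At an unadjusted p under 0.05 in both comparisons, 24 probes had opposite signs, or 41 without the weak arrays.

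Across probes, which are not independent replicates, the log2 differences from control at 0.004 and 0.12 mg/L correlated with a Pearson r of 0.660 and a Spearman rho of 0.637. The comparisons share their controls. Unchanged groups simulated against the same controls gave a mean r of 0.492, and the covariance was 0.134 against a simulated 0.0803, whose middle 95% ran from 0.00372 to 0.192. For 0.004 and 1.85 mg/L r was 0.427 (rho 0.410), with a covariance of 0.0715 against a simulated 0.0773. For 0.12 and 1.85 mg/L r was 0.354 (rho 0.383), with 0.0677 against 0.0785. None of the 3 covariances lay outside the simulated range. The simulation moved arrays between slides, while in the real groups every slide holds all 4 groups. Deviations of arrays on the same slide with other replicate numbers had a mean r of 0.167, against -0.061 between slides. Slide differences may therefore widen the simulated range, and lying inside it decides little. With 3 of the controls for either dose, averaged over the ways to divide them, r was 0.138 for 0.004 and 0.12 mg/L, -0.0996 for 0.004 and 1.85 mg/L and -0.0925 for 0.12 and 1.85 mg/L.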

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

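The tests of the 2 weak arrays were chosen after their signal had been seen. So were the splits within slides and all splits without the weak arrays. The tests of 1.85 mg/L replicate 1 single out that array, so they too followed a look at the signal. Their predictions were written before their own values were seen. The splits of all arrays for the planned results were not chosen after seeing the signal. For the weak arrays, a first test by the nearest group profile, on which solvent control replicate 1 lay nearer to 1.85 mg/L (r = 0.197) than to its own group (0.071), was replaced after its result was seen. In each group, every array was compared with the rest of its group on 5 measures of quality and on the named probes. Of 80 such groups of values, 16 held an array far from the others, where chance gives about 4.

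Most of these concern 2 arrays. In solvent control, replicate 1 had 49.68% of spots well above background (others 89.56 to 96.66), a median correlation with the other arrays of 0.812 (others 0.968 to 0.978) and a duplicate-spot difference of 0.411 (others at most 0.0934), and DM02756P2 stood at 0.26 (others 1.77 to 2.30). At 0.004 mg/L, replicate 2 had 79.44% (others 91.54 to 96.55), a median correlation of 0.892 (others 0.970 to 0.977), a spike-in slope of 0.865 (others 0.990 to 1.053), a duplicate-spot difference of 0.465 (others 0.0592 to 0.0911), and DM05878P1 at -5.25 (others -3.97 to -3.46).

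A poor measurement on these arrays is a candidate explanation. Duplicate spots share 1 RNA sample, so a biological difference would leave them as close as elsewhere, yet the smaller of the 2 values, 0.411, lies above the highest of the other 21 arrays, 0.170. A wrong label was tested on probes at least 2-fold apart between 2 groups in the fit without these arrays. Replicate 2 of 0.004 mg/L lay nearer to its own group than to 1.85 mg/L on 78.8% of 104 probes, which argues against a 1.85 mg/L sample. Solvent control replicate 1 lay nearer to control than to 1.85 mg/L on 47.7% of 109 probes and than to 0.12 mg/L on 37% of 27 probes. Set against 1.85 mg/L, the other control arrays gave 60% to 94.6%. The 0.004 mg/L arrays other than the weak one gave 47% (replicate 3) to 97.1%. Set against 0.12 mg/L, 4 control arrays with 10 or more probes each gave 62.5% to 66.7%, and control replicate 4 had 7 of 7. Both values of replicate 1 lie below those of every other control array. Neither differs from an even share past p = 0.05 by an exact binomial test. That test treats probes as independent, which they are not, and its reference is an even share rather than that of the other controls. A wrong label therefore stays open for that array, and no biological explanation was tested.

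At 1.85 mg/L, replicate 1 had a duplicate-spot difference of 0.170 (others 0.0573 to 0.0932), and DM04941P2 stood at -2.32 (others -5.97 to -5.12). With the probes in 4 equal bins by signal, the dimmest lay above the mean of the other 1.85 mg/L arrays by a median of 1.305 and the brightest at -0.12. The gap of 1.425 on the log2 scale met the prediction for a raised signal of dim probes on this array. The bins came from the mean of the other 1.85 mg/L arrays, which favours such a gap, and no other array was put to this test. How much of the gap comes from the binning is therefore not known. It was not nearest to another group (0 of 1 tests): over 203 probes past the F test its profile correlated at 0.703 with its own group and at most 0.042 with another, which argues against a wrong label. What raised the dim signals was not tested. Without this array as well as the weak ones, 365 probes differed at 1.85 mg/L.

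Of the other values far from their group, 3 were on 1.85 mg/L replicate 5. That array lay nearer to its own group than to control on 48 of 80 probes (60%), the lowest share of the 1.85 mg/L arrays, and the cause was not tested. DM04295P1 stood at 0.22 on 0.004 mg/L replicate 5 (others 2.84 to 4.39). The spike-in slope was 1.059 on 0.12 mg/L replicate 1 (others 0.956 to 0.980). On 1.85 mg/L replicate 5, DM04653P1 stood at -1.45 (others -2.94 to -2.46), DM08360P3 at 3.96 (others 5.41 to 5.95) and DM02677P3 (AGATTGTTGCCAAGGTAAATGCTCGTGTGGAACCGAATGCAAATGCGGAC), named after its values were seen, at 5.83 (others 4.75 to 5.14).

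Other splits of the same arrays into groups of the same sizes were counted, 100 for each result with the real one included. For 1.85 mg/L against control, 1 split, the real one, gave as many as 83 probes, and the highest other gave 15; without the weak arrays 1 split gave 422 and the highest other 38. For 1.85 against 0.004 mg/L the real split was the 1 with the highest count, 82 against 1, and without the weak arrays 264 against 26. At 0.004 mg/L, 2 splits gave 5 or more (highest other 15), but without the weak arrays 5 splits gave 6 or more (highest other 87), so chance cannot be excluded there. At 0.12 mg/L, 2 splits gave 9 or more (highest other 12), and without the weak arrays 2 gave 29 or more (highest other 93). For the F test 2 splits gave 97 or more (highest other 334), and for opposite changes 1 split gave 1 (highest other 0). Splits of all 3 groups rarely call a probe at both doses, so chance stays open for that 1 probe. Only the split with the highest count was examined for each result. Those with 87, 93 and 334 probes followed the slides: that with 87 put all 4 arrays of slide 1 in one group, that with 93 put the 4 of slide 1 against the 4 of slide 2, and that with 334 put 6 of slide 1 in one group and 5 of slide 2 in another. That with 15 at 0.004 mg/L did not gather a slide in one group. With the slide as a block the real counts were 5 at 0.004 mg/L, 8 at 0.12 mg/L and 103 for the F test, and 5, 33 and 268 without the weak arrays.

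Splits were then drawn again with arrays exchanged only within a slide, so that slides could not raise the counts of other splits. At 1.85 mg/L against control 1 of 100 gave 83 or more (highest other 4), and without the weak arrays 1 of 100 gave 422 (highest other 26). This argues against chance for this comparison, though 100 splits can give no smaller share than 1 of 100. Between 1.85 and 0.004 mg/L 1 of 100 gave 82 (highest other 0), but without the weak arrays 3 of 100 gave 264 or more, the highest 1006. That split put 1.85 mg/L replicates 2 and 4 with most of the 0.004 mg/L arrays and 0.004 mg/L replicate 3 with most of the 1.85 mg/L arrays, for a reason that was not tested. In the label test above, 0.004 mg/L replicate 3 lay nearer to its own group than to 1.85 mg/L on 47% of 217 probes. Set against 0.004 mg/L, 1.85 mg/L replicate 2 lay nearer to its own group on 65.8% of 161 probes, but replicate 4 on 95.8% of 95. For the F test 1 of 100 gave 97 (highest other 1), which argues against chance. At 0.004 mg/L 2 of 100 gave 5 or more (highest other 19), and without the weak arrays 2 of the 36 possible gave 6 or more (highest other 17), so chance cannot be excluded there. At 0.12 mg/L 4 of 100 gave 9 or more (highest other 33), and without the weak arrays 1 of the 36 possible gave 29 (highest other 4).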

How the results depend on the processing

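Settings without the weak arrays, without 3 arrays and with row and column were chosen after seeing the data; the others were fixed before. Values below are probes called against control at the low, middle and high dose, then between 1.85 and 0.004 mg/L, in the F test and with opposite changes, against 5, 9, 83, 82, 97 and 1. The cause of a shift was not tested unless stated.

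Normexp gave 0, 1, 14, 25, 24 and 0, and array weights 683, 93, 1003, 2882, 2095 and 15. An adjusted p under 0.10 gave 9, 16, 207, 137, 152 and 2, and an unadjusted p under 0.05 with a 1.5-fold change 655, 727, 733, 1022, 959 and 19, by construction. Quantile normalization gave 11 at 0.004 mg/L and 2 opposite changes, the deposited values 12 at 0.004 mg/L, 16 at 0.12 mg/L and 2 opposite changes, and only probes well above background on all arrays 196 at 1.85 mg/L. Only the groups compared gave 0, 2 and 23 against control. Slide 1 alone, with fewer arrays, gave 0 at 0.004 mg/L, 8 at 1.85 mg/L, 5 between 1.85 and 0.004 mg/L, 17 in the F test and 0 opposite changes; slide 2 alone gave 0, 0, 0, 1, 1 and 0 and slide 3 alone 0 for all 6. Without the weak arrays 29, 422, 264 and 294 passed at 0.12 mg/L, at 1.85 mg/L, between 1.85 and 0.004 mg/L and in the F test. Without 3 arrays these were 34, 365, 221 and 218, without the weak arrays with the slide as a block 33, 383, 278 and 268, and with quantile normalization 39, 485, 242 and 306. Row and column gave 2, 2, 4, 47, 44 and 0. Without the weak arrays these terms gave 3, 6 and 28 against control and 78 between 1.85 and 0.004 mg/L. In the fit of row and column with all arrays, the 83 probes at 1.85 mg/L had a median absolute log2 difference of 1.108, against 1.14. All 83 signs were kept, the median SE was 0.241, against 0.223, and 4 stayed past the threshold. The sizes changed little, but the terms also use degrees of freedom, and what ended the calls was not separated.

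No pairing by replicate number was seen beyond that by slide. Deviations of same-numbered arrays correlated above 0.1 in 18 of 33 pairs (mean r 0.125), no more than other pairs on the same slide (20 of 33, mean 0.167), against a mean of -0.061 between slides. Whether replicates were paired in exposure or handling cannot be read from these values. With the number as a block 5 probes passed at 0.12 mg/L and 24 at 1.85 mg/L; the other counts, 4, 57, 73 and 1, moved by less than 1.5 times. Without the weak arrays this block gave 2, 2, 71, 177, 122 and 0.

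Leaving out 1 array at a time gave 3 to 47 probes at 0.004 mg/L, 2 to 22 at 0.12 mg/L, 26 to 159 at 1.85 mg/L, 52 to 236 between 1.85 and 0.004 mg/L, 59 to 200 in the F test and 1 to 1 opposite changes. The count at 1.85 mg/L moved by over 1.5 times for 15 of 23 arrays, 13 downward. It was 29, 31, 51, 26, 28 and 41 without 1.85 mg/L replicates 6, 5, 3, 4, 1 and 2; 34, 43, 46, 158 and 51 without control replicates 5, 6, 4, 1 and 2; 54, 51 and 159 without 0.004 mg/L replicates 4, 1 and 2; and 53 without 0.12 mg/L replicate 4. At 0.004 mg/L it was 47 without 0.004 mg/L replicate 5 and 10, 8, 3, 8 and 3 without control replicates 6, 3, 4, 1 and 2. At 0.12 mg/L it was 17 without 0.004 mg/L replicate 5, 4, 2, 2 and 3 without 0.12 mg/L replicates 5, 6, 4 and 1, and 16, 2, 22 and 14 without control replicates 3, 4, 1 and 2. The F test gave 59 and 61 without 1.85 mg/L replicates 6 and 4 and 200 without control replicate 1.

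The correlation of log2 differences between 0.004 and 0.12 mg/L (0.660) was 0.138 with the controls divided between the doses, 0.169 with them so divided without the weak arrays, 0.956 over F-test probes, and 0.478 to 0.769 without single arrays. That between 0.004 and 1.85 mg/L (0.427) was -0.0996, -0.00312 and -0.0109 in these settings and 0.311 to 0.540 without single arrays. That between 0.12 and 1.85 mg/L (0.354) was -0.0925 and -0.0762 with the controls divided, 0.0317 over F-test probes and 0.161 to 0.494 without single arrays.

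None of the 28 differences of named probes, 4 of them from the contrast added later, turned round in any of the 14 settings run on them or without single arrays, where 112 of 644 missed the threshold. The probes were picked among large called differences in these same arrays, with 1 sign on every slide. Fits of a single slide could therefore not turn them round, and the other settings were unlikely to. All 28 stayed past the threshold with the deposited values, 27 with the slide as a block, 25 with quantile normalization, 22 with the replicate block, 13 with row and column, 10 with normexp, 3 within slide 1 alone and 0 within slides 2 and 3 alone. The gene lists were not run, as no probe has a gene name, nor was the brightest probe per gene, as each ID has 1 probe. With 49.68% and 79.44% of spots well above background, the weak arrays can show little for dim probes.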

Other observations

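The contrast of 0.004 and 0.12 mg/L with control and 1.85 mg/L, the probes named for it and its GC, slide, batch and row-and-column tests were chosen after the result was seen, as was the comparison of 0.004 mg/L replicate 5 with its group. Its pairing test and its splits came after the contrast but were set before their own values were seen, and the tests of shared sequence and probe length before theirs. With all arrays, 80 probes separated the mean of the 2 lower doses from the mean of control and 1.85 mg/L, 25 higher and 55 lower, and without the weak arrays 131, 46 higher and 85 lower, with 79 shared. Quantile normalization gave 41 higher and 43 lower, the deposited values 43 and 44, normexp 6 and 18, and quantile normalization without the weak arrays 64 and 70, so the balance of directions moved with the scaling. Array weights gave 353 higher and 865 lower, 1218 in all, and slides 1, 2 and 3 alone, with fewer arrays, 7, 6 and 0. Among the lower ones, DM05878P1 was 15.2-fold below (log2 difference -3.93 ± 0.46, SE; adjusted p = 6.32e-05), and among the higher ones DM04941P2 was 6.28-fold above (log2 difference 2.65 ± 0.42, SE; adjusted p = 0.00175) and DM02756P2 5.31-fold above (adjusted p = 0.000833). For these 2 higher ones, control lay nearer to the lower doses than to 1.85 mg/L (means of DM04941P2 -2.41, -0.85, -1.18 and -4.92 from control to the highest dose, of DM02756P2 1.77, 2.78, 2.82 and -0.99). Their differences from control at 0.004 and 0.12 mg/L, 1.56 ± 0.59 and 1.23 ± 0.61 for DM04941P2 and 1.00 ± 0.49 and 1.05 ± 0.52 for DM02756P2 (log2, SE), did not pass the threshold (adjusted p = 0.579 and 0.619, and 0.588 and 0.619). On 61 of the 80, and on 99 of the 131 without the weak arrays, the mean at 1.85 mg/L lay beyond control, and on 19 and 32 between control and the lower doses. Control lay nearer to the lower doses than to 1.85 mg/L on 31 and 55, and on 65 and 97 the lower doses differed in 1 direction from both control and 1.85 mg/L at an unadjusted p under 0.05. Of the 80, 48 were also called between 1.85 and 0.004 mg/L, 18 at 1.85 mg/L against control, 9 at 0.12 mg/L and 5 at 0.004 mg/L, and 37 had an unadjusted p of 0.05 or more at 1.85 mg/L against control. No single array moved the count by over 1.5 times (57 to 117).

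Several technical explanations were set against this pattern. The larger of the 2 other ways to pair the 4 groups gave 2 probes with all arrays and 12 without the weak ones. Both other ways divide 0.004 from 0.12 mg/L, between which 0 probes had been called. Their low counts therefore partly restate that likeness. Adding row and column on the slide as terms kept 98.3% of the median size over the 80 probes, and 97.5% stayed past the threshold after each array's trend with probe GC content was removed. With the slide as a block 92.5% of the 80 stayed past the threshold and 87 probes passed in all. Of 100 splits of the arrays 2 gave 80 or more; the other, with 471, put all 8 arrays of slide 1 on one side. With arrays exchanged only within slides, 1 of 100 splits, the real one, gave 80, and the highest other gave 0. Both sets of splits exchanged arrays of all 4 groups, so a difference of the highest dose alone could also set the real split apart. On 61 of the 80 probes the mean at that dose lay beyond control. The splits therefore cannot show that the 2 lower doses in particular stand apart. Row and column as terms left 53 of the 80 past the threshold, normexp 24. A batch of exposure, RNA or labelling shared by the 2 lower doses stays open, since the labels name 0 such batches, and so does a response of the animals to low doses, which is a hypothesis here.

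Replicate 5 of 0.004 mg/L may differ from its group at this dose. Without it 47 probes were called against control, and on 7 of the 39 probes at least 2-fold apart in a fit without it and the weak arrays (17.9%) it lay nearer to its own group than to control. These probes were found with the array left out, which favours such a result, and its cause was not tested.

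Some probes overlap in sequence, which allows a check within the array. Over 53 pairs on the same strand with at least 30 identical bases in a row, the log2 differences at 1.85 mg/L without the weak arrays correlated with r = 0.832 (Spearman 0.934), against a middle 95% of -0.263 to 0.272 for 10000 sets of random pairs (permutation p = 0.0001, the smallest these can give). Probes that overlap as reverse complements of each other, 84 pairs, had r = 0.661 (Spearman 0.488; random -0.214 to 0.217; permutation p = 0.0001). Labelled RNA of 1 strand binds only 1 probe of such a pair, so both strands may be represented in the labelled material or in transcripts from the same place; no test separated these.

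Probes of 60 bases were not called at another rate than those of 50 bases at 1.85 mg/L without the weak arrays: 50 of 1676 against 372 of 12244, an odds ratio of 0.981 (95% interval 0.712 to 1.33; Fisher's exact test, two-sided p = 1). With all arrays it was 17 of 1676 against 66 of 12244, an odds ratio of 1.89 (1.04 to 3.27, Fisher's exact test, p = 0.0262), so the difference seen with all arrays was not found without the weak ones. The prediction of another rate had named neither set of arrays, and with all arrays it was met. Fisher's test treats probes as independent, which they are not.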
